A study of Mus musculus with 10 samples.

How the data were processed

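RNA came from pulverized femurs of 10 mice, was extracted with TRIzol, depleted of ribosomal RNA and sequenced on an Illumina platform, per the labels' protocols. Per the submitters' processing notes, STAR 2.5.2b and DESeq2 1.14.1 were used with the mouse genome mm10; other settings are not given in the sources used here. The deposited table holds one score per gene and library: a count divided by a DESeq2 size factor and rounded to whole numbers, per the file headers and the values themselves. It lists 27179 genes with Entrez identifiers, symbols and exon coordinates. Of these, 6903 were at 0 in every library, and 847 had no symbol; 0 columns lacked a sample. Groups, sex and replicate numbers came from the sample titles, and genotype from the labels. Ages of 3 and 4 weeks are given for the series and not per mouse.

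Because the deposited values were rounded after scaling, whole reads could not be recovered in every library, and no count test was run: the planned edgeR and DESeq2 alternatives were not possible. The normalized counts that 1 read is worth were estimated from which whole numbers are skipped or doubled among values up to 150 in each library. They ran from 0.846 to 2.19, the highest in female WT 3. Totals divided by this value gave 18.1 M to 30.6 M estimated reads, or 12.9 M to 30.6 M without Rn45s. A value of 0 was given a limit of 3 reads, 2.54 to 6.58 normalized counts. This limit covers counting error only. No pair of replicates in a group was a copy: equal values were found in at most 1.12% of tested genes.

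Genes with 10 or more normalized counts in 5 or more of the 10 libraries were tested, 14362 in all. Values were taken as log2(normalized count + 1), so that fold changes of low genes are understated. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust moderation, a labelled-sex covariate and Benjamini-Hochberg adjustment over genes, with calls at an adjusted p under 0.05. Within-sex effects, their difference (labelled males minus females) and the spread were estimated from the means of the 4 groups in all 10 libraries. The sex difference had genotype as covariate. Fgfr1 and Fgf23 were tested by exact two-sided permutation of genotype within labelled sex, 120 arrangements. Each mouse gave 1 library.

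Before the data were examined, 26 gene lists, the tests and the rule for named genes were fixed. The lists held 14 of bone and signalling biology, 11 of other cell types and 1 of immediate early genes, with 455 of 457 entries matched in the table. Lists with 5 or more tested genes (22) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. The erythroid, neutrophil, B cell and T or NK cell lists had too few. The rule named Fgfr1 and Fgf23; the 10 genes with the strongest rise and fall among those past the threshold for genotype in all mice (none passed); up to 4 members of each list with the smallest p; up to 5 genes of the interaction (none passed); and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Members "adjusted over the list alone" had Benjamini-Hochberg adjustment within their list. Any other named gene is said to have been chosen after its values were seen.

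The tests were run on simulated data for genotype in all mice (14205 genes, with the gene means and gene spreads of the real libraries). Noise was independent between genes and had the same spread in all libraries. The real libraries differ in spread and their genes correlate, so the rates that follow need not hold for them. The limma test recovered 60.2% of 98 genes changed 2-fold and 91.4% of 93 genes changed 4-fold, and 14 of its 158 calls (8.86%) were genes simulated without change. Alternatives tried were pseudocounts of 0.5 and 5, no filter or a filter at a mean of 50, quantile normalization, rescaling without mitochondrial and hemoglobin genes, array weights, no sex covariate, the replicate number as a block, single-sex fits, muscle and marrow marker covariates, and leaving out each library in turn. The marrow covariate was the mean log2 value over the genes of the erythroid, neutrophil and B cell lists, which lay near the floor. After the data were seen, fits without female WT 3 and male WT 1, and without these and the library labelled male mutant 2, were added, as were lists without shared genes and the omission of each library for lists within and between the sexes.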

Results

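Ribosomal RNA-depleted RNA was sequenced from the pulverized femurs of 10 mice aged 3 or 4 weeks. Of these, 5 mice carried 1 copy of an Fgfr1 allele with the amino acid change N330I (Fgfr1+/N330I, here called mutant), and 5 were wild-type (WT) littermates. FGFR1 is a receptor for fibroblast growth factors, and the series title names a mouse model of osteoglophonic dysplasia, a skeletal disorder with disturbed phosphate handling. By label, the groups held 3 female mutants, 3 female WT mice, 2 male mutants and 2 male WT mice. Values were DESeq2-normalized counts for 27179 genes. Totals ran from 24904802 to 39606608 normalized counts per library, and the estimated reads behind them from 18.1 M to 30.6 M.

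Markers of bone cells were well represented, and those of blood cells were nearly missing. Genes of the osteoblast list held 2.1% to 8.09% of the counts outside the ribosomal RNA gene Rn45s, and those of the macrophage list 0.389% to 0.759%. Hemoglobin genes together reached 6 to 79 normalized counts per library. In each library, the erythroid, neutrophil, B cell and T or NK cell lists each held less than 0.012% of the counts.

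A few libraries stood apart. Rn45s, the ribosomal RNA precursor, took 28.8% of the counts of female WT 3 and 0.149% to 0.428% in the other 9 libraries. Male WT 1 had relatively few reads on genes with long exon sequence: its log2 deviation changed by -1.78 per log10 of exon bases, against -0.64 to 0.29 in the others. This slope also differed by labelled sex: -1.78 to -0.02 in the male-labelled libraries and 0.008 to 0.29 in the female-labelled ones. The library labelled male mutant 2 had 7972 normalized counts of Xist, the RNA of the inactive X chromosome, and 4 of the Y-linked gene Ddx3y. The other 3 male libraries had 14 to 48 of Xist and 1558 to 1936 of Ddx3y, and the 6 female libraries had 14007 to 19641 of Xist. That library is named by its label throughout.

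**Figure D1:**
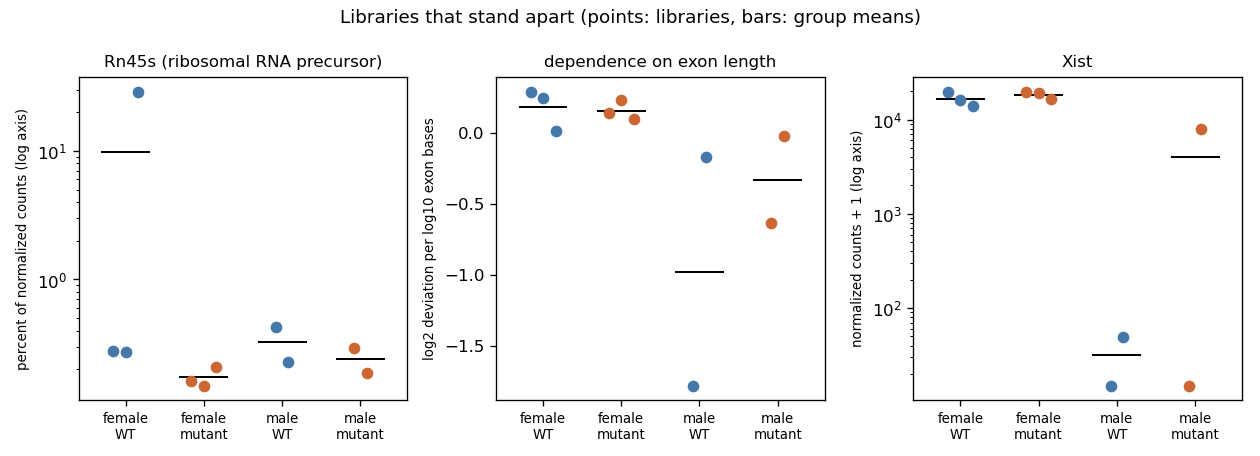
Share of normalized counts on Rn45s (percent, log axis), slope of log2 deviation on log10 exon bases, and Xist (normalized counts + 1, log axis) for each of the 10 libraries by group, with black bars for group means. Female WT 3 lies at 28.8% Rn45s, male WT 1 at a slope of -1.78, and the library labelled male mutant 2 at 7972 Xist counts.

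The series names the axis from Fgfr1 through Fgf23 to phosphate, so these 2 genes were compared first between mutant and WT mice. Fgf23, the bone-derived hormone that makes the kidney excrete phosphate, was higher in the mutants. It stood at 5.6 ± 3.78 normalized counts in the mutants (SD, n = 5) and 1 ± 1 in WT mice (SD, n = 5). All mutant libraries lay at 2 to 11 and all WT libraries at 0 to 2, so the groups met at 2. The difference was 1.70 ± 0.49 (SE) on the log2(count + 1) scale, with an exact two-sided permutation p of 0.0167 within labelled sex, the smallest that the 120 arrangements can give, and 0.0333 after adjustment over the 2 genes. With a pseudocount of 5 in place of 1 the difference was 0.77, at the same exact permutation p.

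These Fgf23 values rest on an estimated 30 reads in the 5 mutant libraries and 5 reads in the 5 WT libraries. A count of 0 allows up to 2.61 normalized counts in female WT 2 and up to 6.58 in female WT 3 (3 reads; counting error alone). Fgf23 (chromosome 6, 127072902 to 127081408, mm10) was too low for the test across all genes. With female WT 3 and male WT 1 both left out, the difference was 1.64 ± 0.63 with an exact permutation p of 0.0667. Within females the difference was 2.16 ± 0.67, at the smallest exact permutation p that 3 against 3 libraries allow, 0.1. Within labelled males it was 1.00 ± 0.58, with an exact permutation p of 0.333, the smallest for 2 against 2.

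Fgfr1 (chromosome 8, 25518772 to 25575714), the mutated gene, was measured at 11124.8 ± 1973.7 normalized counts in the mutants and 8082.4 ± 2706.7 in WT mice (SD, n = 5 each). The difference of 0.52 ± 0.26 log2 had an exact permutation p of 0.05, which did not pass the threshold of under 0.05. The limma test gave an adjusted p of 0.783. Without male WT 1 the difference was 0.31, and without male WT 1 and female WT 3 it was 0.28. Leaving out female mutant 1 raised the difference to 0.66 (exact permutation p = 0.0333), and leaving out female WT 1 raised it to 0.63 (exact permutation p = 0.0333). Gene counts do not separate the mutant from the WT allele.

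**Figure D2:**
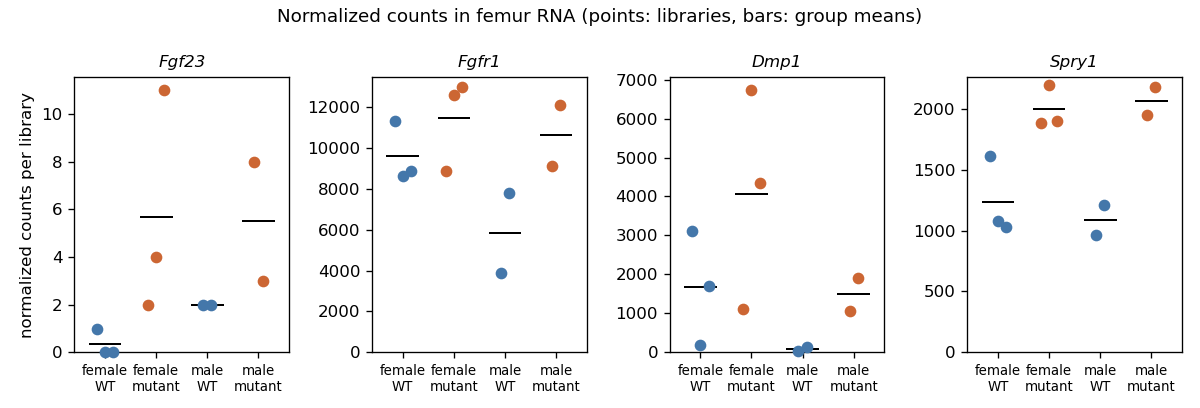
Normalized counts of Fgf23, Fgfr1, Dmp1 and Spry1 in each of the 10 libraries (points) by labelled sex and genotype, with black bars for group means. Fgf23 lies at 2 to 11 in the mutants and 0 to 2 in WT mice, and Spry1 at 1885 to 2197 in the mutants and 960 to 1608 in WT mice.

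Across the transcriptome, genotype moved no single gene past the threshold. By camera at a preset correlation, the FGF receptor and ligand list, the FGF and MAPK feedback list and the lists of osteocyte and osteoclast markers rose as groups in the mutants, and interferon-stimulated genes and endothelial markers fell as groups. In all, 9 of the 22 tested lists rose and 3 fell, but 0 of the 22 passed with a correlation estimated from these libraries, and 0 with fry. Other splits of the same libraries within labelled sex called a median of 9 lists, against 12 in the real split. Of 60 splits, the real one included, 2 gave as small a camera p for FGF and MAPK feedback and 3 for FGF receptors and ligands. The number was 7 for osteocyte, 11 for osteoclast, 7 for interferon-stimulated and 16 for endothelial genes. Of 14362 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.237. At an unadjusted p under 0.05 there were 907 genes, 530 higher and 377 lower in the mutants, where 0.05 of the tested genes is 718.1. Other splits within labelled sex gave a median of 426 such genes and up to 1698. At least 907 came in 13 of the 60 splits. Without male WT 2 there were 1585 at an unadjusted p under 0.05, and 0 past the threshold.

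Targets that FGF signalling induces through MAPK, many of which restrain the pathway, rose in the mutants. The median of the 18 measured genes was 0.38 log2 (camera adjusted p = 4.92e-07; adjusted p = 0.408 with an estimated correlation), and 17 of the 18 estimates were above 0. Without male WT 1 the median was 0.22, and the list still passed. None of the 18 passed over all genes, and 2 passed adjusted over the list alone. These were Spry1, an inhibitor of receptor tyrosine kinase signalling, at 0.80 ± 0.14 (1885 to 2197 normalized counts in mutants, 960 to 1608 in WT; list-alone adjusted p = 0.00368), and the transcription factor Etv5 at 0.46 ± 0.13 (list-alone adjusted p = 0.0459). Spred1 stood at 0.52 ± 0.16 and the MAPK phosphatase gene Dusp4 at 0.37 ± 0.13, neither past the test.

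The list of FGF receptors and ligands also rose, with a median of 0.38 over 10 measured genes, 7 of them estimated above 0 (camera adjusted p = 0.00122; adjusted p = 0.408 with an estimated correlation), and 0.23 without male WT 1. The call was also lost with the marrow covariate (0.29, adjusted p = 0.0787) and without female WT 3, male WT 1 and the library labelled male mutant 2 together (0.22, adjusted p = 0.0551). Of its 10 genes, 0 passed over all genes and 2 adjusted over the list alone. Fgf1 averaged 147.6 ± 81.2 normalized counts in mutants and 44.4 ± 29.8 in WT mice (SD, n = 5 each), a difference of 1.81 ± 0.33 log2 with a list-alone adjusted p of 0.00262. Fgf10 differed by 1.59 ± 0.50 (list-alone adjusted p = 0.0473). Fgf18, a ligand that acts on cartilage and bone, had 1.32 ± 0.51 and did not pass. The 3 estimates below 0, named after their values were seen, were those of the receptor genes Fgfr3 (-0.86 ± 0.62) and Fgfr2 (-0.26 ± 0.44) and of Fgf7 (-0.02 ± 0.21), none past the test.

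Osteocyte markers rose, with a median of 0.94 over 10 measured genes, all of them estimated above 0 (camera adjusted p = 0.00055; adjusted p = 0.408 with an estimated correlation). The median of the osteocyte markers was 0.50 without female mutant 3, 0.50 without female WT 3 and 0.63 without female WT 1. Without the genes shared with other lists, it was 0.26 and the call was lost (adjusted p = 0.0877), as it was without female WT 3, male WT 1 and the library labelled male mutant 2 together (0.59, adjusted p = 0.0553). No member passed on its own, over all genes or adjusted over the list alone. The values were 2.66 ± 0.87 for Dmp1, a matrix protein gene of osteocytes, 1.99 ± 0.86 for Phex, which when lost raises FGF23, 2.51 ± 1.15 for Mepe and 1.88 ± 0.99 for the Wnt inhibitor Dkk1. WT libraries differed widely in these genes: Dmp1 lay at 44 to 3114 normalized counts in WT mice and 1051 to 6726 in mutants. The phosphate and mineralization list, which shares Dmp1, Phex and Mepe with the osteocyte list, rose by a median of 0.16 over 19 genes, 12 of them estimated above 0 (camera adjusted p = 0.00551; adjusted p = 0.549 with an estimated correlation). Its median was -0.10 in females (adjusted p = 0.979) and 0.74 in labelled males (adjusted p = 3.58e-05; adjusted p = 0.513 with an estimated correlation). In females the list passed as lower without female WT 2 (median -0.09, adjusted p = 0.0467). The phosphate difference between the sexes was 1.07 (interaction adjusted p = 0.000132; adjusted p = 0.5 with an estimated correlation), and 0.70 without female mutant 1. In all mice the phosphate call was lost without female WT 2 (median 0.16), male WT 2 (0.08) or the library labelled male mutant 2 (0.12). The median in all mice was 0.29 without female mutant 1. The phosphate call in all mice was also lost with the marrow covariate (0.19, adjusted p = 0.276). It was lost too without female WT 3, male WT 1 and the library labelled male mutant 2 together (0.07, adjusted p = 0.108). Ank, a transporter that exports pyrophosphate, was the list's 1 member to pass adjusted over the list alone (0.68 ± 0.16, list-alone adjusted p = 0.032), at 4390 to 8552 normalized counts in mutants and 3139 to 4050 in WT mice.

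Osteoclast markers rose by a median of 0.60 over 18 genes, 16 of them estimated above 0 (camera adjusted p = 1.57e-06; adjusted p = 0.547 with an estimated correlation). Without male WT 1 the median was 0.32, and the list still passed. None passed over all genes and 6 passed adjusted over the list alone. The fusion genes Dcstamp (1.27 ± 0.37) and Ocstamp (1.76 ± 0.51), the receptor gene Oscar (1.64 ± 0.47) and the matrix protease gene Mmp9 (1.78 ± 0.52) each had a list-alone adjusted p of 0.0314. Mmp9 reached 115096 normalized counts in male mutant 1 and 19436 to 32343 in the other mutants, and 5010 to 29876 in WT mice. Male mutant 1 had a list mean of 12.20 log2, and the other 4 mutants 10.62 to 11.02.

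Osteoblast markers did not pass (median 0.13 over 20 genes, camera adjusted p = 0.211), nor did markers of growth plate cartilage (-0.04 over 20 genes, adjusted p = 0.63) or hypertrophic cartilage (-0.05 over 14 genes, adjusted p = 0.936; the camera direction was up where the median was below 0). With the marrow covariate, both cartilage lists passed as lower, growth plate at a median of -0.60 (adjusted p = 9.79e-06) and hypertrophic at -0.51 (adjusted p = 0.00971). That covariate rests on few counts: the erythroid, neutrophil and B cell lists had library means of 1.46 to 2.49 log2(normalized count + 1). The growth plate list passed as lower with the muscle covariate too (-0.28, adjusted p = 0.0266). Osteoblast markers passed as higher without female mutant 1 (0.38, adjusted p = 0.00248), female WT 1 (0.37, adjusted p = 0.00563) or female WT 3 (0.24, adjusted p = 0.0363). The osteocalcin genes Bglap and Bglap2 had values of 1.69 ± 0.65 and 1.91 ± 0.63, and Col2a1, the main cartilage collagen gene, had -1.55 ± 0.69, none past the test. Chondromodulin (listed as Lect1), an angiogenesis inhibitor of cartilage, passed adjusted over its list alone (-3.72 ± 0.76, list-alone adjusted p = 0.0127), with 0 to 10 normalized counts in mutants and 3 to 339 in WT mice. The Wnt list rose by a median of 0.09 over 21 genes, 15 of them estimated above 0 (camera adjusted p = 0.0234; adjusted p = 0.669 with an estimated correlation), with values of 1.44 ± 0.35 for Notum and 0.91 ± 0.34 for Axin2 that did not pass. Its median was -0.23 in females (adjusted p = 0.979) and 0.71 in labelled males (adjusted p = 0.000761; adjusted p = 0.513 with an estimated correlation). In labelled males it was 1.136 without male mutant 1, 0.33 without male WT 1 and 0.16 without the library labelled male mutant 2. The Wnt difference between the sexes was 0.87 (interaction adjusted p = 0.00166; adjusted p = 0.5 with an estimated correlation). It was 0.39 without the library labelled male mutant 2, and its call was lost without male WT 1 (0.64, adjusted p = 0.124). The Wnt call in all mice was lost in 13 of 25 alternative settings. Among them were the fits without female mutant 2 (median 0.17), female mutant 3 (0.06), female WT 2 (0.08), male WT 1 (0.06), male WT 2 (0.13) or the library labelled male mutant 2 (-0.02). The Wnt median was 0.38 without female mutant 1, 0.33 without female WT 1, 0.19 without female WT 3 and 0.26 without male mutant 1. BMP and TGF-beta genes (median 0.09, adjusted p = 0.936) and ER stress genes (-0.06, adjusted p = 0.346) did not pass; the first passed as lower with the marrow covariate (-0.12, adjusted p = 0.0384) and the second with the muscle covariate (-0.15, adjusted p = 0.00839).

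Cell cycle genes rose by a median of 0.20 over 20 genes (camera adjusted p = 8.29e-05; adjusted p = 0.549 with an estimated correlation), with values of 0.58 ± 0.14 for Kif11 and 0.60 ± 0.17 for Mki67 that did not pass singly. Without male WT 2 the cell cycle median was 0.06 and the call was lost (adjusted p = 0.156), and it was 0.11 without male mutant 1 and 0.33 without male WT 1. Hypoxia and glycolysis genes rose by 0.17 over 17 genes, all estimated above 0 (adjusted p = 0.00122; adjusted p = 0.547 with an estimated correlation). The hypoxia call was lost without female mutant 1 (median 0.13, adjusted p = 0.0548) and with array weights (0.10, adjusted p = 0.0532), and the median was 0.29 without female mutant 3. Here the carbonic anhydrase gene Car9 had 0.87 ± 0.37 and did not pass. Interferon-stimulated genes fell by 0.49 over 18 genes, with 17 estimates below 0 (adjusted p = 4.92e-07; adjusted p = 0.408 with an estimated correlation), and the median was -0.31 without female WT 3. Isg15 had -0.97 ± 0.31, Irf7 -0.75 ± 0.25 and Oasl2 -0.67 ± 0.20, none past the test over all genes or adjusted over the list alone.

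Skeletal muscle and endothelial markers also moved as groups by camera at the preset correlation. Their medians were 2.10 and -1.73 in females, and -0.35 and 0.05 in labelled males, where neither passed. As small a camera p came in 14 of 60 splits within labelled sex for muscle and in 16 for endothelial markers. Skeletal muscle markers rose by a median of 1.16 over 17 genes (camera adjusted p = 1.1e-06; adjusted p = 0.547 with an estimated correlation), with values of 1.65 ± 0.65 for Ttn and 1.74 ± 0.72 for Atp2a1 that did not pass singly. The muscle median was 0.66 without female mutant 3 and 1.89 without male mutant 1. The muscle call was lost with the marrow covariate (0.31, adjusted p = 0.153) and, by construction, with the muscle covariate (-0.10, adjusted p = 0.807). The muscle list made up at most 0.057% of the counts outside Rn45s. Endothelial markers fell by a median of 1.01 over 16 genes, all estimated below 0 (adjusted p = 8.27e-06; adjusted p = 0.547 with an estimated correlation). Kdr had -0.99 ± 0.40 and Emcn -1.45 ± 0.65, and neither passed. Female mutant 1 had the lowest endothelial mean, 6.52 log2, against 8.71 to 10.14 in the other 9 libraries, and without it the endothelial median was -0.36 (adjusted p = 0.000815). Immediate early genes, which respond to tissue handling, fell by a median of 0.24 (adjusted p = 0.00611; adjusted p = 0.577 with an estimated correlation), with values of -0.56 ± 0.21 for Atf3 and -0.71 ± 0.33 for Dusp1. The immediate early call was lost without male mutant 1 (median -0.16, adjusted p = 0.232) or male WT 2 (-0.19, adjusted p = 0.207), with array weights (-0.13, adjusted p = 0.0549) or without a sex covariate (adjusted p = 0.118), and the median was -0.41 without female WT 2.

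Lists of macrophage (-0.13, adjusted p = 0.169), megakaryocyte (-0.10, adjusted p = 0.936), adipocyte (0.08, adjusted p = 0.936), stromal (0.28, adjusted p = 0.169) and tendon, ligament and periosteum markers (0.02, adjusted p = 0.63) did not pass; macrophage markers passed as lower without male mutant 1 (-0.22, adjusted p = 0.0464). Single members passed adjusted over their list alone: the lipase gene Lpl among the adipocyte markers (-0.58 ± 0.13, list-alone adjusted p = 0.0205) and the fibril-associated collagen gene Col14a1 among the tendon markers (1.23 ± 0.31, list-alone adjusted p = 0.0406). The erythroid, neutrophil, B cell and T or NK cell lists had too few measured genes for camera. Among their measured members, the beta-globin gene Hbb-bs (-2.18 ± 0.50, list-alone adjusted p = 0.00563; 3 to 12 normalized counts in mutants, 11 to 50 in WT mice) and the spectrin gene Sptb (1.38 ± 0.44, list-alone adjusted p = 0.0224) passed adjusted over the list alone. Lcn2 (1.60 ± 0.74), Blnk (-0.51 ± 0.21) and Cd4 (0.73 ± 0.40) did not.

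**Figure D3:**
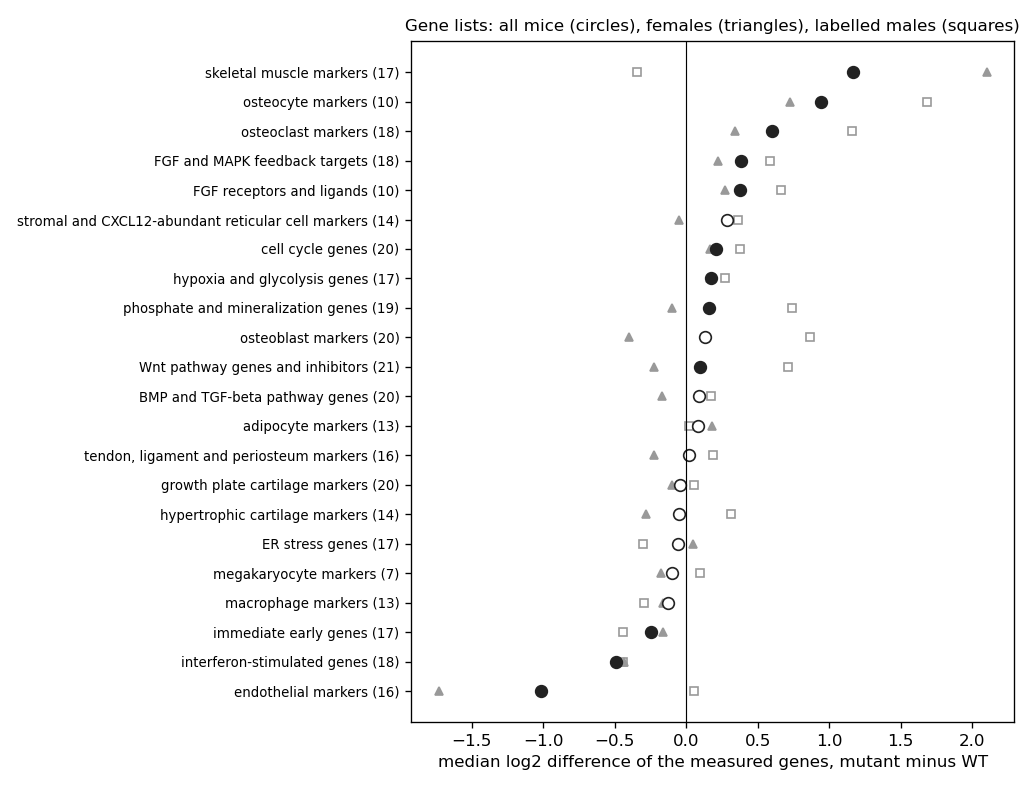
Median log2 difference (mutant minus WT) of the measured genes of the 22 tested lists, with the number of genes in brackets, in all mice (circles, filled where the camera adjusted p with the preset correlation was under 0.05), females (triangles) and labelled males (squares). The 12 filled lists run from -1.01 for endothelial to 1.16 for skeletal muscle markers, and 0 of them passed with an estimated correlation.

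**Figure D4:**
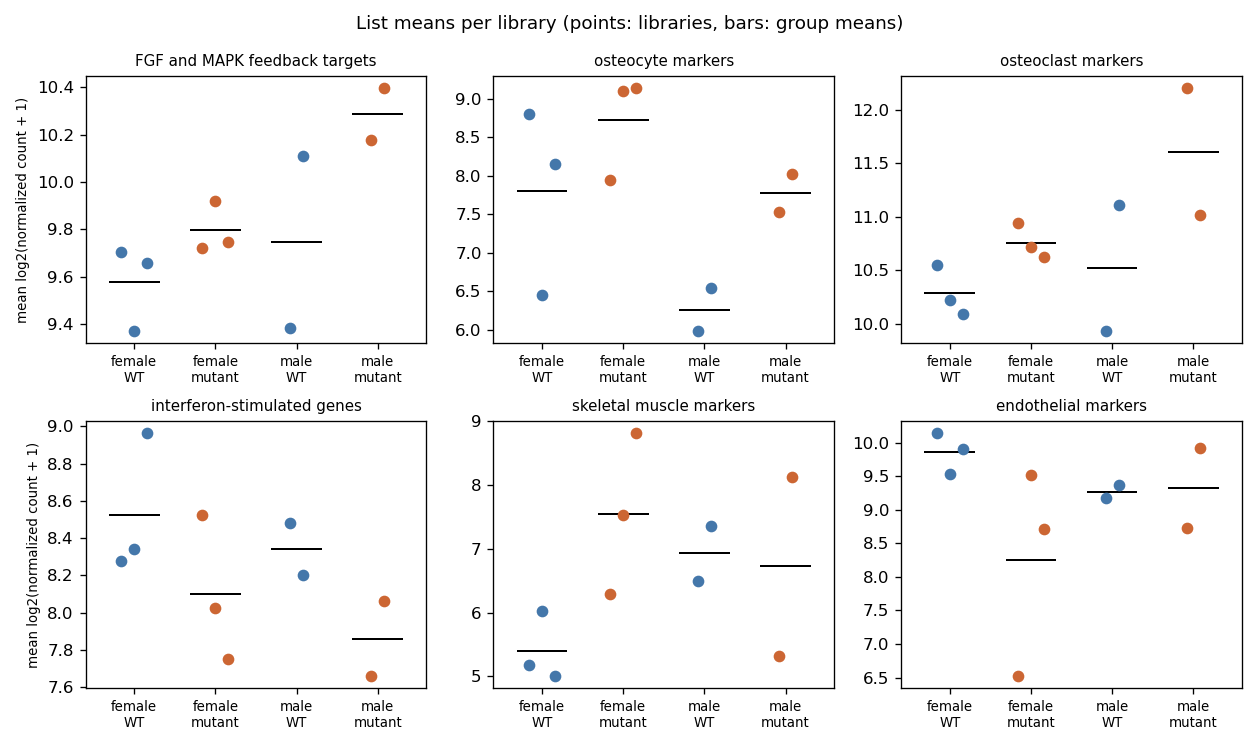
Mean log2(normalized count + 1) over the genes of 6 lists in each library (points) by labelled sex and genotype, with black bars for group means. Male mutant 1 is highest for osteoclast markers (12.20), and female mutant 1 is lowest for endothelial markers (6.52).

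Both labelled sexes were present in each genotype, so the genotype effect was also taken within females and within labelled males. The library labelled male mutant 2 was female by Xist (7972 counts) and by Y-linked genes (a sum of 5). The contrast within labelled males and the interaction may therefore mix sex with genotype. In females, 2 genes rose in the mutants and 0 fell (limma). Both lie side by side on chromosome 18 and were singled out after their values were seen: Eif3j2, a second gene for a subunit of translation initiation factor 3 (2.74 ± 0.25, adjusted p = 0.0196), and the gene model Gm3650 (4.26 ± 0.41, adjusted p = 0.0196). Eif3j2 had 149 to 207 normalized counts in female mutants and 20 to 32 in female WT mice, and 132 to 218 in the 4 male libraries of both genotypes. Gm3650 was at 0 in all 3 female WT libraries and at 10 to 20 in the other 7. Eif3j2 has a near-identical copy, Eif3j1, so its level is uncertain. Leaving out 1 library at a time left 0 or 1 of these calls.

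In females the muscle list was 2.10 higher by median (camera adjusted p = 9.47e-18; adjusted p = 0.545 with an estimated correlation) and the endothelial list 1.73 lower (median -1.73, adjusted p = 5.09e-14; adjusted p = 0.545 with an estimated correlation). Without female mutant 1 the endothelial median in females was -0.78. In labelled males the medians were -0.35 for muscle and 0.05 for endothelial markers, and neither passed. The muscle list in labelled males passed as higher without male mutant 1 (1.03, adjusted p = 0.00397) and as lower without the library labelled male mutant 2 (-1.55, adjusted p = 0.000124). Labelled males had 0 genes past the threshold by limma (smallest adjusted p = 0.296; 1193 genes at an unadjusted p under 0.05). The 1193 became 643 without male WT 1, 148 with array weights and 6114 without male WT 2, where male WT 1 stands alone and 4362 genes passed; 1 gene passed without female WT 2 (Eno1b, named after its value was seen) and 1 without male mutant 1 (Xist). Without male mutant 1, the library labelled male mutant 2 stands alone in its group. The Xist call there reflects its 7972 counts of Xist and is no sign of a genotype effect. In labelled males osteocyte markers rose by a median of 1.69 (camera adjusted p = 0.00307; adjusted p = 0.513 with an estimated correlation) and osteoclast markers by 1.16 (adjusted p = 2.81e-05; adjusted p = 0.513 with an estimated correlation), with the library labelled male mutant 2 counted as labelled. The osteoclast call in labelled males was lost without male mutant 1 (median 0.58, adjusted p = 0.0999), and the median was 0.47 without male WT 1 and 1.80 without the library labelled male mutant 2. The osteocyte call in labelled males was lost without male WT 1 (0.99, adjusted p = 0.0539) or male WT 2 (1.63, adjusted p = 0.0693). The median was 0.77 without the library labelled male mutant 2, and 0.68 without female mutant 2, female mutant 3, female WT 1 or female WT 3, where the set of measured genes changes. By camera, 10 lists passed in females and 15 in labelled males, and 0 in either with an estimated correlation. Of these, 7 of 10 and 13 of 15 lost the call when at least 1 library was left out. In females the medians were 0.73 for osteocyte markers (adjusted p = 0.0379; adjusted p = 0.627 with an estimated correlation) and 0.34 for osteoclast markers (adjusted p = 0.00943; adjusted p = 0.785 with an estimated correlation). In females the osteocyte call was lost without female mutant 2 (0.53), female mutant 3 (0.36), female WT 2 (-0.07), male WT 1 (0.73), male WT 2 (0.73) or the library labelled male mutant 2 (0.31). Leaving out a male-labelled library changes no gene's difference in females, only the shared spread and the set of measured genes. The osteoclast call in females was lost without female mutant 1 (0.30), and the median was 0.22 without female WT 3.

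The test of the difference between the sexes' genotype effects called 0 genes by limma (smallest adjusted p = 0.331; 563 at an unadjusted p under 0.05, and on leaving out 1 library 275 without female WT 1, 353 and 352 without female mutants 1 and 3, 342 without female WT 3 and 4993 without male WT 2). By camera it called 12 lists, and 0 with an estimated correlation; 9 of the 12 lost the call when at least 1 library was left out. Endothelial markers had the highest median difference, 1.90 log2 (adjusted p = 1.53e-05; adjusted p = 0.5 with an estimated correlation), and 0.86 without female mutant 1 or 1.13 without the library labelled male mutant 2. Osteoblast markers had 1.37 (labelled males minus females; 0.87 in labelled males and -0.40 in females, interaction adjusted p = 0.000183; adjusted p = 0.5 with an estimated correlation), and 0.89 without female mutant 1 or 0.73 without the library labelled male mutant 2. In females the osteoblast list passed as lower without female mutant 2 (-0.54), female mutant 3 (-0.52) or female WT 2 (-0.87, adjusted p = 3.57e-05). In labelled males the osteoblast median was 1.76 without male mutant 1, and the call was lost without male WT 2 (1.00, adjusted p = 0.0693) or the library labelled male mutant 2 (0.40, adjusted p = 0.19). Muscle markers had the lowest, -2.34 (adjusted p = 3.9e-07; adjusted p = 0.5 with an estimated correlation). The muscle difference was -1.12 without male mutant 1 and -3.55 without the library labelled male mutant 2, and its call was lost without male WT 2 (-2.26, adjusted p = 0.087). Without male WT 2 the test called 2686 genes, and without female WT 2 or male mutant 1 it called 1 (Eno1b and Xist). The Xist call again reflects the 7972 counts of Xist in the library labelled male mutant 2. Male-labelled and female-labelled libraries carry different series of library names. The interaction and the sex difference therefore cannot be told apart from a difference between these series.

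Male-labelled and female-labelled libraries were compared to check the labels and to size the split between them. Xist was lower in the male-labelled libraries (-7.49 log2, adjusted p = 0.0125), with the library labelled male mutant 2 as the exception. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 1558 to 1936, 1159 to 1625, 511 to 673 and 335 to 436 normalized counts in 3 male-labelled libraries, and at 0 to 4 in the other 7. Immediate early genes rose in the male-labelled libraries by a median of 1.74 (camera adjusted p = 3.51e-10; adjusted p = 0.764 with an estimated correlation), Dusp1 by 2.01 (limma adjusted p = 0.00825), Zfp36 by 1.67 (adjusted p = 0.00362) and Egr2 by 1.74 (adjusted p = 0.00111). The library labelled male mutant 2, female by Xist and Y-linked genes, had an immediate early mean of 12.07 log2, within the 11.08 to 12.15 of the other male-labelled libraries and above the 9.86 to 10.35 of the female-labelled ones. Cell cycle genes rose by 0.70 (camera adjusted p = 8.09e-08; adjusted p = 0.946 with an estimated correlation). Markers of hypertrophic cartilage fell by 0.95 and the Wnt list fell by 0.66 (both adjusted p = 0.0431; adjusted p = 0.946 with an estimated correlation). Both calls were lost without female mutant 3, female WT 1, male WT 1 or male WT 2 (Wnt median -0.43 without female WT 1), and that of hypertrophic cartilage also without female WT 3 or male mutant 1.

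Over all genes the split was wide: 2886 genes passed by limma, 1358 higher and 1528 lower in the male-labelled libraries. Leaving out 1 library at a time gave 965 to 4044 genes, 965 without female WT 2, 4044 without male WT 2 and 3362 without the library labelled male mutant 2. Single omissions that moved the count by over 1.5 times were those of female mutants 1, 2 and 3 (1732, 1330 and 1658), female WT 1, 2 and 3 (1169, 965 and 1227) and male mutant 1 (1316).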

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

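Tests on Fgf23, on male WT 1, on Xist, on the count of genes at an unadjusted p under 0.05 and on the best list of each split were chosen after the results were seen; the other counts of splits were planned. In 61 sets of values, a single library stood far from the rest in 9, where chance flags about 1 in 20.

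Fgf23 was higher in the mutant libraries by 1.70 ± 0.49 log2. The low read yield of female WT 3 does not account for it, since the exact permutation p without that library was 0.0333, and with the muscle list mean as a covariate the difference stayed at 1.46 ± 0.57. More osteocytes in the mutant material remain a candidate explanation: relative to the mean of the other osteocyte genes, the Fgf23 difference was 0.59 ± 0.63 (exact permutation p = 0.367), although with that mean as a covariate it was 1.44 ± 0.65. The osteocyte mean itself differed by 1.11 ± 0.53 (exact permutation p = 0.1). Fgf23 lay at 0 to 11 normalized counts, so the added 1 shrinks its difference, which was 2.14 with a pseudocount of 0.5. The value relative to the osteocyte mean may therefore understate what remains of the Fgf23 difference. An effect of the mutation on Fgf23 per osteocyte, or on the number of osteocytes sampled, was not separated by these data.

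Male WT 1 lay far from the other WT libraries in its slope on exon length, -1.78, next to -0.18 in male WT 2. The other 9 libraries had slopes of -0.64 to 0.29, negative in the male-labelled ones and positive in the female-labelled ones. Its mean correlation with the other libraries was 0.926, against 0.952 to 0.966. With the trend on exon length removed from every library, it was 0.949, still the lowest (0.956 to 0.970 in the others) but closer to them than their range, so whether loss of reads on long transcripts sets the library apart stays open. Depth does not explain it, with 27.5 M estimated reads against 18.1 M in the shallowest library. Genotype does not either, since male WT 2, at -0.18, lay within the range of the mutants (-0.64 to 0.23). What made the RNA differ was not tested, and the library also had the highest WT mean for ER stress genes, 12.59 log2.

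The library labelled male mutant 2 had 7972 counts of Xist, next to 48 in the closest other male-labelled library. A mixture of male and female RNA is argued against by a sum of 5 over 4 Y-linked genes, against 4029 or more in the other male-labelled libraries and up to 8 in female ones. An exchange with a female-labelled library of this series is argued against too, since the lowest Xist among those was 14007. A single wrong sex label, or an exchange with a sample from outside, stays open and may also bear on its genotype label, which these counts cannot check.

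Other values far from their group were the Rn45s share of female WT 3 (28.8%, next 0.428%) and its 18.1 M estimated reads (27.5 M in the next WT library). Female mutant 3 had a mean of 6.84 log2 for FGF receptors and ligands (next 6.36), male mutant 1 had 12.20 for osteoclast markers (next 11.02), and female WT 2 had 6.48 for growth plate cartilage markers (next 7.44).

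The genotype effect differed between the labelled sexes for 12 lists by camera at the preset correlation, and for 0 with an estimated correlation, and 9 of the 12 lost the call when at least 1 library was left out. Of these, 3 turned below 0: FGF and MAPK feedback without male WT 1 (-0.04), osteoclast without male mutant 1 (-0.05) or male WT 1 (-0.03) and cell cycle without male WT 2 (-0.10). The median differences (labelled males minus females) were 0.23 for FGF and MAPK feedback, 1.07 for phosphate and mineralization, 1.37 for osteoblast, 0.53 for osteoclast and 0.81 for hypertrophic cartilage genes. They were 0.87 for Wnt, 0.65 for BMP and TGF-beta, -0.30 for ER stress, 0.24 for cell cycle, -2.34 for muscle, 1.90 for endothelial and 0.58 for stromal genes. The lists are not all separate: the phosphate, osteoblast and hypertrophic lists share Alpl, Ibsp, Spp1 and Pth1r. The fit without shared genes was not run for the difference between the labelled sexes.

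Other splits of the libraries show what grouping alone can give. For genotype in all mice, all 60 splits within labelled sex gave at least the real 0 genes (highest other 8), which any split does and which decides nothing. In 13 of 60 splits there were at least the real 907 genes at an unadjusted p under 0.05 (highest other 1698), and in 18 of 60 at least the real 12 lists (highest other 17), so chance cannot be excluded for the 907 genes and the 12 lists. For the FGF and MAPK feedback list, 2 of 60 splits, the real one included, gave as small a camera p (-log10 p of 7.35, highest other 8.25). For this list taken alone that share is under 0.05, but another split gave a smaller p, so chance is not excluded. The FGF and MAPK feedback list was the 1 list of 22 with under 0.05 of the splits. In 30 of the 60 splits some list ranked as high among the splits, so over the 22 lists chance cannot be excluded. Its call was also lost with an estimated correlation (adjusted p = 0.408) and with fry (adjusted p = 0.288). In females, 2 of the 10 splits gave at least the real 2 genes (highest other 6), and 10 splits are too few for a share under 0.05. For the sex difference, 1 of 100 splits, the real one, gave as many as 2886 genes (highest other 40). A random grouping of the libraries is thus an unlikely source of this count. Labelled sex and the series of library names divide the libraries alike, so the test cannot tell sex from name series.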

How the results depend on the processing

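The fits without 2 or 3 libraries, the lists without shared genes, and the omissions for lists within and between the sexes were chosen after the data were seen. Fgf23 kept its direction in all 18 alternatives, at 0.77 (pseudocount 5) to 2.14 (pseudocount 0.5). It missed the threshold under the replicate block (1.70, exact p = 0.0625, the smallest that 5 pairs allow), without female WT 3 and male WT 1 (1.64, exact p = 0.0667) and without these and the library labelled male mutant 2 (1.88, exact p = 0.1), where fewer libraries allow fewer arrangements. Leaving out 1 library gave 1.34 to 1.99 for Fgf23 and 0.31 to 0.66 for Fgfr1, whose lowest value was 0.21, without the 3 libraries. Replicate numbers showed no sign of pairing in females, where same-numbered deviations from the group mean correlated at -0.32, -0.29 and 0.00118. In labelled males, with 2 libraries per group, both pairs have the same correlation by construction (0.221). Of 10 libraries, 4 correlated best with their own number, but the male-labelled ones match or miss together, so this count says little about pairing. The block left 0 genes in females and 0 in all mice. Genotype in all mice called 11 genes with array weights, 1 with the marrow covariate (Angptl1, named after its value was seen) and 0 in the other settings. In females the count of 2 became 1 with a pseudocount of 5, a filter at a mean of 50 or quantile normalization, 7 with array weights, 0 with the 6 female libraries alone and 0 in both fits without 2 or 3 libraries, and was 0 to 1 on leaving out 1 library. In labelled males and for the interaction, leaving out 1 library gave 0 to 4362 and 0 to 2686 genes, the highest without male WT 2, where male WT 1 is assumed to vary like the other groups; the sex difference gave 965 to 4044. The count of 12 lists became 0 with an estimated correlation. Of 550 list values, 42 lost and 9 gained a call (3 of the gains for osteoblast, 2 for growth plate and 1 for hypertrophic genes, lower with the marrow covariate at -0.599 and -0.508 for both cartilage lists), 440 kept both direction and side of the threshold, and 65, of 11 lists, turned the sign of the median (40) or the camera direction alone. Of these 11 lists, the muscle and Wnt lists were called. With array weights the medians of the lists that turned in either way were 0.0286 for ER stress, -0.0434 for growth plate, 0.0243 for hypertrophic and -0.0412 for tendon genes; with a filter at a mean of 50, 0.00148 for adipocyte and -0.102 for megakaryocyte genes; without shared genes, 0.0889 for BMP and TGF-beta and -0.0216 for hypertrophic genes; without a filter, -0.0497 for hypertrophic genes; with quantile normalization, 0.00202 for ER stress genes. With the marrow covariate they were -0.123 for BMP and TGF-beta, -0.0287 for Wnt, 0.125 for adipocyte, -0.508 for hypertrophic, 0.0861 for macrophage, -0.35 for osteoblast and -0.0408 for tendon genes. With the muscle covariate they were -0.0979 for muscle (by construction), -0.0486 for BMP and TGF-beta, -0.0135 for adipocyte, -0.00252 for hypertrophic and -0.129 for megakaryocyte genes. Without female WT 3 and male WT 1 they were 0.0165 for BMP and TGF-beta, 0.0137 for ER stress, -0.0733 for growth plate, -0.035 for hypertrophic, 0.0122 for megakaryocyte and -0.0341 for tendon genes. Without the 3 libraries they were -0.1001 for BMP and TGF-beta, 0.0287 for ER stress, -0.0672 for Wnt, -0.184 for hypertrophic, 0.00347 for macrophage, -0.171 for osteoblast and -0.0127 for tendon genes. Leaving out 1 library gave medians of -0.0156 to 0.378 for Wnt, -0.144 to 0.384 for osteoblast, -0.275 to 0.0879 for growth plate, -0.225 to 0.132 for hypertrophic, -0.0257 to 0.193 for BMP and TGF-beta, -0.141 to 0.0562 for ER stress, -0.18 to -0.028 for megakaryocyte, -0.0628 to 0.31 for adipocyte and -0.0773 to 0.128 for tendon genes. All 2247 values of the 99 list members named by the rule stayed on the same side of the threshold, and 43, of 13 genes, turned sign. With array weights these were Asns 0.0184, Col10a1 0.13, Ebf1 -0.0104, Tnfsf11 -0.0314 and Tspan33 0.273; with quantile normalization, Cd22 -0.00992. With the marrow covariate they were Cd22 -0.429, Cd4 -0.00594, Dlx3 -0.333, Ebf1 -0.148, Mmp8 0.812, S100a8 0.242, Sgms2 -0.315 and Vwf -0.41, and with the muscle covariate Cd22 -0.251, Mmp8 0.59, Tspan33 0.121 and Vwf -0.0518. Without female WT 3 and male WT 1 they were Ebf1 -0.0608, Mmp8 0.0507 and Tspan33 0.116, and without the 3 libraries Cd22 -0.126, Ebf1 -0.203, Mmp8 0.479 and Vwf -0.228. Leaving out 1 library gave -0.12 to 0.259 for Ebf1, -0.0307 to 0.294 for Lck, -0.359 to 0.399 for Tspan33, -0.191 to 0.275 for Cd22, -0.549 to 0.389 for Mmp8 and -0.0545 to 0.755 for Vwf. What turned these values was not tested. The count tests were not run. Depth limits Fgf23, at 5 estimated WT reads.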

Other observations

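The tests in this part on genes beside Fgfr1 were planned before their result was seen, and the test on Eif3j1 was chosen afterwards. With array weights, which give less influence to libraries that fit poorly, limma called 11 genes for genotype in all mice. The weights ran from 0.088 for male WT 1 to 2.35 for male WT 2 and 3.24 for female mutant 2. The calls thus lean more on some libraries than on others. These 11 genes were singled out here after their values were seen. Higher in mutants were Ace, the angiotensin-converting enzyme gene (1.42 ± 0.15, adjusted p = 0.0212), the imprinted RNA H19 (1.36 ± 0.15, adjusted p = 0.0212), Scube1 (1.96 ± 0.24), Tenm3 (0.97 ± 0.14) and Lsp1 (0.46 ± 0.07). Lower were the muscle atrophy ubiquitin ligase gene Fbxo32 (-0.88 ± 0.10, adjusted p = 0.0212), Vgll3 (-0.64 ± 0.07), Eya2 (-1.03 ± 0.15), Angpt4 (-1.67 ± 0.22), Arhgap25 (-0.67 ± 0.09) and AU020206 (-1.07 ± 0.15). Without weights none of them passed. There, Ace stood at 538 to 1316 normalized counts in mutants and 300 to 539 in WT mice, H19 at 33138 to 76540 and 12103 to 46116, and Fbxo32 at 304 to 580 and 788 to 960 (adjusted p = 0.237 for Ace and Fbxo32, 0.247 for H19).

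An allele bred from another strain could carry neighbouring sequence that changes nearby genes. Of 54 tested genes within 5 Mb of Fgfr1, 3 (5.56%) had an unadjusted p under 0.05 for genotype, against 6.32% of the other 14308, with a one-sided Fisher's exact p of 0.672. No excess beside Fgfr1 was found.

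Gm3650 and Eif3j2 were low in all 3 female WT libraries, and in none of the other 7, WT males included. The copy Eif3j1 went the other way, with 370 to 450 normalized counts in the female WT libraries against 265 to 341 in the others. A candidate explanation for Eif3j2 is that its reads were assigned to Eif3j1 in these 3 mice, as a sequence variant would do; the lowest of the 3, 370, lay above the highest of the others, 341. Whether this bears on Gm3650, which ends at 43475271, was not tested. It would not account for Myot on the same chromosome (start 44334074, against 43475418 for Eif3j2), which was chosen after its values were seen. Myot, a muscle gene, had 2 to 6 normalized counts in the female WT libraries and 14 to 32 in the other 7 (adjusted p = 0.886 in females by limma). The muscle list mean was 5.00 to 6.03 log2 in female WT mice and 6.29 to 8.82 in female mutants. Male mutant 1, at 5.33, had 29 counts of Myot. Whether muscle content sets the Myot values was not tested. Whether the 3 mice share a litter is not given in the labels, and the same contrast is the genotype contrast in females.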
